A study of Caenorhabditis elegans with 12 samples.

How the data were processed

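RNA from whole Caenorhabditis elegans worms at the late L4 larval stage was sequenced in 12 samples, 3 in each of 4 genotypes. These were wild-type N2, the eat-2(ad465) mutant, the acs-20(tm3232) mutant and the eat-2; acs-20 double mutant. Worms were grown at 20 °C. Per the labels, total RNA was isolated with a Zymo RNA MiniPrep kit and made into Illumina libraries. The deposited values were raw read counts per gene in 1 table per sample, with no normalization by the authors. Each table also held HTSeq's summary lines for reads assigned to no gene. The processing notes name FastQC 0.11.5, TopHat2, HTSeq and DESeq2 without their roles. The genome build, the annotation release, the strand setting and the library kit are not given in the sources used here. Gene symbols and chromosomes came from an Ensembl annotation of the WBcel235 build, so no coordinates are given. With the strand setting unknown, a gene that overlaps a coding gene on the opposite strand may carry some of its neighbour's reads. Near-identical paralogs may lose reads, as reads with more than 1 position were set apart in a summary line. Among genes named in the text, the first applies to R03C1.1, T13F3.6, Y42G9A.3, Y43F8B.3, Y48E1B.8, ZK512.7, acs-22, alh-8, asg-1, clec-3, col-19, col-41, dhgd-1, far-3, fat-5, gba-1, gpdh-1, nas-37, nhr-178, pho-6, sdz-24, srlf-34 and vit-2, and the second to vit-3, vit-4, pud-1.2 and the abu and nspc families.

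The tables listed 46739 genes, of which 43720 had a symbol in the annotation and 3019 did not. Counts in genes came to 7116623 to 12016769 per sample. A gene with no counts in a group was given a floor of 3 counts over that group, and its fold change is stated as at least the ratio to this floor. This ratio is not a 95% limit. For F48C1.9 against wild-type it was 186 in acs-20 and 5.13 in eat-2, with exact 95% lower limits of 150 and 3.65. For a group total of 1 to 3 counts the ratio is given with an exact 95% binomial interval. Intervals and floors cover counting error only. Genes were filtered with edgeR's filterByExpr by genotype at its defaults (a minimum count of 10 and a minimum total of 15). This left 14390 genes, 461 of them without a symbol, which held 99.82 to 99.89% of the counts in genes.

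Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors ran from 0.921 to 1.1. One negative binomial model with 4 group means was fitted to all 12 samples, which left 8 residual degrees of freedom, and the common biological coefficient of variation was 0.1526. Robust quasi-likelihood tests were made for 6 contrasts: each mutant strain against wild-type, the double mutant against each single mutant, and the interaction. The interaction is the effect of eat-2 in acs-20 mutants minus its effect in animals with an intact acs-20. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Adjusted p-values for single genes in the text come from these edgeR tests unless another method is named. CPM values (counts scaled to a common library size) used the TMM factors. Log2 CPM values of libraries used a prior count of 2, and fitted fold changes edgeR's default prior count. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between samples only.

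Gene lists written from general knowledge of the organism before the data were examined numbered 43, and 41 had at least 5 tested members. They were tested with camera (limma 3.58.1) with the correlation between genes estimated from the data, adjusted over the lists. The tests, the lists and the rule for naming genes were also fixed before the data were examined. By that rule the text names the mutated genes and, per contrast, up to 8 genes with the highest and 8 with the lowest log2 fold change. These had to be changed, to have an average log2 CPM of at least 3 and, except for the interaction, to have no overlap between the samples of the groups compared. At most 2 genes per family and 2 genes known only by a sequence name were taken in each direction. The rule adds the 3 changed members with the smallest p in each list that was called, and a set of sentinel genes. Of the sentinels, sod-3 was not among the tested genes. The same number of members of lists that were not called, the muscle genes myo-1 and myo-2, the propionate-pathway genes, and families of genes sharing a name were chosen after their values were seen. Families with at least 8 tested members, 180 in number, were compared with all tested genes by a one-sided hypergeometric test, adjusted over families.

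Alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, a minimum change of 2-fold, fits to the compared samples alone, the replicate number as a block, camera with a preset correlation of 0.01, the fry test, and leaving out each of the 12 samples in turn. Added after the data had been seen were a stage score as a covariate, the ribosomal RNA share as a covariate, and leaving out the ribosomal RNA genes. The stage score was the main axis of the deviations of replicates from their group means, with vitellogenin and ribosomal RNA genes left out. Calls were also counted over other splits of the samples. The overlap of the single mutants was compared with simulations of unchanged groups sharing a simulated wild-type group. In these all 12 libraries were drawn from the wild-type means, in 100 draws with genes independent and 100 with deviations of whole libraries. The procedure was tested on simulated data: counts shaped like these, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 89% of the 4-fold changes in eat-2 against wild-type, 90% in acs-20 against wild-type and 80% in the interaction. For 2-fold changes these shares were 53, 57 and 34%. The share of false calls was 6.58, 7.55 and 5.79%. Genes were drawn independently in this test, so these shares leave out deviations of whole libraries. In the unchanged groups drawn with such deviations, up to 744 genes were called in a single mutant against wild-type. The contrast of acs-20 with wild-type called 318 in the data.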

Results

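Whole worms of 4 genotypes were compared by RNA sequencing at the late L4 stage: wild-type, eat-2, acs-20 and the eat-2; acs-20 double mutant, with 3 libraries each. eat-2 encodes a nicotinic acetylcholine receptor subunit needed for fast pumping of the pharynx, and its mutants eat slowly and serve as a model of dietary restriction. acs-20 encodes a fatty acid transport protein with acyl-CoA synthetase activity that is needed for the barrier of the cuticle. Counts in genes were 10164893, 10762387 and 10842659 in the wild-type libraries, 8711477, 8253781 and 10630057 in eat-2, 9517911, 9265492 and 7116623 in acs-20, and 7558637, 10210457 and 12016769 in the double mutant. Between 17882 and 19323 genes had at least 1 read in a library. Values per group are CPM (counts scaled to a common library size) with the SD of 3 libraries, and changes are log2 fold changes with their standard errors.

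The mutated genes were examined first. Reads from eat-2 (WBGene00001133, chromosome II) were too few to check the labels: the 3 libraries of each genotype together held 3 in wild-type, 0 in eat-2, 4 in acs-20 and 1 in the double mutant. The 0 in eat-2 lay within the floor of 3 counts, and the gene was not tested. The acs-20 gene (WBGene00009218, chromosome IV) was read 678 to 1333 times per library. Its counts were 1183, 953 and 1333 in the wild-type libraries, 734, 771 and 1149 in eat-2, 1027, 859 and 780 in acs-20, and 678, 825 and 970 in the double mutant, or 115 ± 22.9, 95.5 ± 11.1, 103.8 ± 8.91 and 79.4 ± 2.32 CPM. Its change in acs-20 against wild-type was -0.15 (SE 0.135, adjusted p = 0.658), so the gene-level count did not separate this genotype from wild-type. A deletion inside a gene need not lower its count. In the double mutant it was lower than in wild-type by a log2 of -0.54 (adjusted p = 0.0148), a call that ended without wild-type replicate 1 (0.0614), wild-type replicate 3 (0.0712) or double mutant replicate 2 (0.0532).

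Libraries carrying the eat-2 mutation lay apart from the others on the first principal component, at 19.9 to 42.8 against -32.3 to -23.5. This component held 36% of the variance and the second 20.6%. On the second, libraries carrying the acs-20 mutation lay at -37.4 to -8.56 and the others at 2.68 to 31.3.

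**Figure D1:**
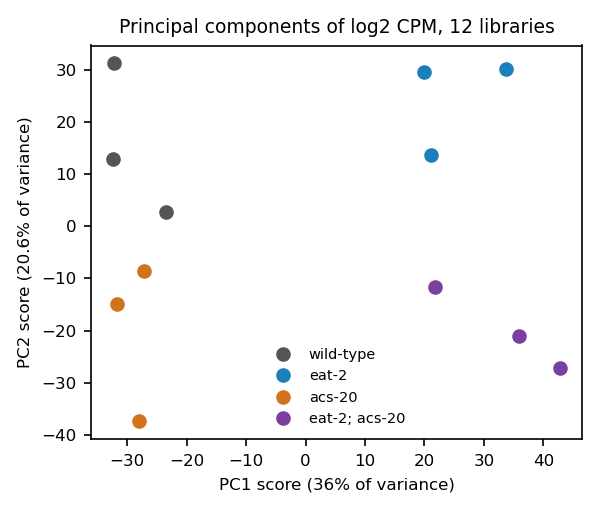
Principal components of log2 CPM in the 12 libraries, PC1 (36% of the variance) on the x axis and PC2 (20.6%) on the y axis, coloured by genotype. The 6 libraries with the eat-2 mutation lie at 19.9 to 42.8 on PC1 and the other 6 at -32.3 to -23.5. On PC2 the 6 libraries with the acs-20 mutation lie at -37.4 to -8.56 and the other 6 at 2.68 to 31.3.

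The comparison of eat-2 with wild-type asked what the eat-2 mutation changes in animals with an intact acs-20. The vitellogenin genes, which encode yolk proteins, were all lower in eat-2. vit-1 went from 236 ± 59 to 7.68 ± 2.21 CPM (SD, n = 3), vit-2 from 2309 ± 1050 to 110 ± 62, and vit-3 from 298 ± 139 to 2.53 ± 1.68. The C-type lectin gene clec-70 rose from 0.83 ± 0.172 to 65.6 ± 14.3, and asm-2, which encodes an acid sphingomyelinase, from 6.62 ± 1.04 to 38.9 ± 6.44. The inositol transporter gene hmit-1.1 fell from 30.7 ± 2.87 to 3.83 ± 1.1. Altogether 1103 of 14390 genes changed, 593 up and 510 down, and 545 of them by at least 2-fold.

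Beside clec-70 (log2 6.28, SE 0.222, adjusted p = 2.06e-09), the highest increases under the naming rule, with its limits on average CPM, overlap of samples and genes per family, were in ugt-18, a UDP-glucuronosyltransferase gene (6.81, SE 0.472), ech-9, an enoyl-CoA hydratase gene (4.81, SE 0.237), T22F3.11 (4.75), the cytochrome P450 gene cyp-13A5 (4.32), the claudin-like gene clc-11 (4.12) and the collagen gene col-41 (4.05). F48C1.9 had no counts in wild-type and was at least 5.13-fold higher in eat-2. Under the same rule the genes that fell furthest were vit-3 (-6.91, SE 0.623), vit-4 (-6.25, SE 0.845), pud-3 (-5.80), pud-1.2 (-5.12, SE 0.251, adjusted p = 7.99e-08), K07H8.16 (-4.72), pqn-2 (-4.42), R03C1.1 (-3.65) and abu-1 (-3.53). Of these calls, those of col-41, pqn-2, R03C1.1 and abu-1 ended when single libraries were left out, with adjusted p up to 0.0665, 0.0759, 0.0593 and 0.0662.

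**Figure D2:**
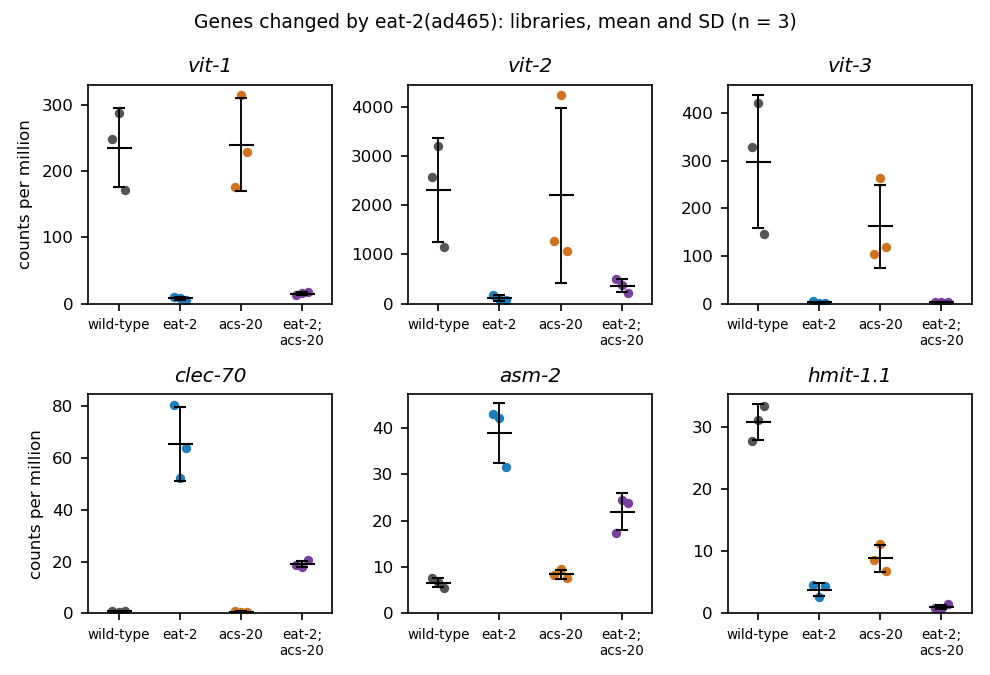
CPM (y axis) of vit-1, vit-2, vit-3, clec-70, asm-2 and hmit-1.1 by genotype (x axis), with 1 dot per library and the mean and SD of 3. vit-1 averages 236 in wild-type and 7.68 in eat-2, while clec-70 goes from 0.83 to 65.6.

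As a group, the 6 vitellogenin genes all fell (6 of 6 when adjusted over the list alone), with a median log2 of -5.25. In sphingolipid metabolism 9 of 26 genes rose and none fell (10 up and 3 down adjusted over the list alone), among them asm-2 (2.55), the ceramidase gene asah-1 (1.34) and the glucosylceramidase gene gba-1 (1.20). Osmolyte synthesis had 5 of 8 genes down and 1 up (the same counts adjusted over the list alone), with hmit-1.1 (-2.995), hmit-1.2 (-1.72) and the glycerol-3-phosphate dehydrogenase gene gpdh-1 (-1.70) falling most clearly. Each of these 3 lists had an adjusted p of 0.0479 with an estimated correlation. None was called with RLE factors (0.0533, 0.0593 and 0.0533 for vitellogenins, sphingolipid metabolism and osmolyte synthesis), and over the leave-one-out fits their adjusted p ran from 0.0186 to 0.157, 0.192 and 0.162, with 9, 11 and 11 of the 12 fits past 0.05.

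Genes of defence and detoxification changed in both directions. Of 102 C-type lectin genes 24 rose and 8 fell (32 and 14 adjusted over the list alone; adjusted p = 0.0572 with an estimated correlation), with clec-76 (3.12) and clec-169 (3.08) among the increases. UDP-glucuronosyltransferase genes had 10 up and 12 down of 56 (adjusted p = 0.988), for example ugt-16 (1.84) and ugt-6 (-1.60). Of 12 targets of the p38 kinase PMK-1 4 rose and none fell (7 and 0 adjusted over the list alone; adjusted p = 0.456), including dod-22 (1.43) and clec-67 (1.29). Lysozyme and saposin-like genes had 8 up and 4 down of 32 (adjusted p = 0.849), and ilys-5 (-1.995) and spp-17 (-1.77) fell. Among 13 phase II targets of the regulator SKN-1, 3 fell and none rose (5 and 0 down and up adjusted over the list alone; adjusted p = 0.084), with gst-10 (-2.35) and gst-4 (-1.56, adjusted p = 0.000139). Of the sentinels for stress of the endoplasmic reticulum and mitochondria, hsp-4 (-0.18, adjusted p = 0.465) and hsp-6 (0.06, adjusted p = 0.842) were not past the threshold, nor was the epidermal peptide gene nlp-29 (0.39, adjusted p = 0.423).

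Fatty acid beta-oxidation had 14 genes down and 3 up of 43 (20 and 3 adjusted over the list alone; adjusted p = 0.456), and acdh-2 (-3.29) and cpt-5 (-1.27) fell while ech-9 rose. The desaturase gene fat-5 rose (1.45), whereas fat-7 (-0.14, adjusted p = 0.722) and the acyl-CoA synthetase gene acs-2 (1.00, adjusted p = 0.166) were not past the threshold. The long noncoding RNA gene tts-1 rose (2.93). Nuclear hormone receptor genes had 18 up and 1 down of 178 (21 and 1 adjusted over the list alone; adjusted p = 0.729), among them nhr-178 (2.07) and nhr-80 (1.08). Markers of stage and tissue were measured beside these. No germline, sperm or oocyte marker was called, and of 9 adult cuticle genes none was called over all genes while 7 were lower when adjusted over the list alone (adjusted p = 0.263). Of 17 body wall muscle genes 5 fell (10 adjusted over the list alone; adjusted p = 0.456). The count of changed genes was 576 without wild-type replicate 1, 724 without wild-type replicate 3, 712 without eat-2 replicate 1 and 708 without eat-2 replicate 3. Decreases outnumbered increases with RLE factors (575 and 564), without a filter (747 and 645), in DESeq2 (767 and 632) and in 5 of the 12 leave-one-out fits, for example without eat-2 replicate 1 (372 and 340).

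The comparison of acs-20 with wild-type asked what the acs-20 mutation changes in animals with an intact eat-2. Genes for antimicrobial peptides of the epidermis rose: nlp-29 from 6.19 ± 1.14 to 63.6 ± 6.73 CPM (SD, n = 3), nlp-31 from 25.5 ± 5.48 to 125 ± 9.52, nlp-34 from 3.51 ± 1.24 to 64.4 ± 13.5, and cnc-2 from 0.496 ± 0.363 to 31.4 ± 9.74. The fatty acid and retinol-binding protein gene far-3 went from 6.91 ± 0.27 to 385 ± 38.6. The gene dod-24 fell from 116 ± 3.31 to 16.17 ± 3.44, and the pharyngeal muscle myosin genes myo-1 and myo-2 fell from 89 ± 13 to 39 ± 8.53 and from 78.7 ± 4.71 to 34.4 ± 10.8. In all, 318 genes changed, 142 up and 176 down, and 199 of them by at least 2-fold.

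F48C1.9, with no counts in wild-type, was at least 186-fold higher in acs-20, and the peptide gene nlp-32 at least 50.4-fold. The other high increases were cnc-2 (log2 5.95, SE 0.459), far-3 (5.80, SE 0.171, adjusted p = 1.8e-10), srlf-34 (5.74), the patched-related gene ptr-22 (4.41), nlp-34 (4.19), cnc-4 (3.63) and T16G1.6 (3.54). Lowest under the naming rule, with its limits on average CPM, overlap of samples and genes per family, were pud-3 (-3.11), dod-24 (-2.84, SE 0.164, adjusted p = 6.1e-07), T13F3.6 (-2.82), ZK512.7 (-2.31), the lectin gene clec-230 (-2.30), the hedgehog-related gene wrt-8 (-1.97), hmit-1.1 (-1.78) and the nematode-specific peptide gene nspc-20 (-1.76). The call of ZK512.7 ended in 4 of the 12 leave-one-out fits, with adjusted p up to 0.0947.

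**Figure D3:**
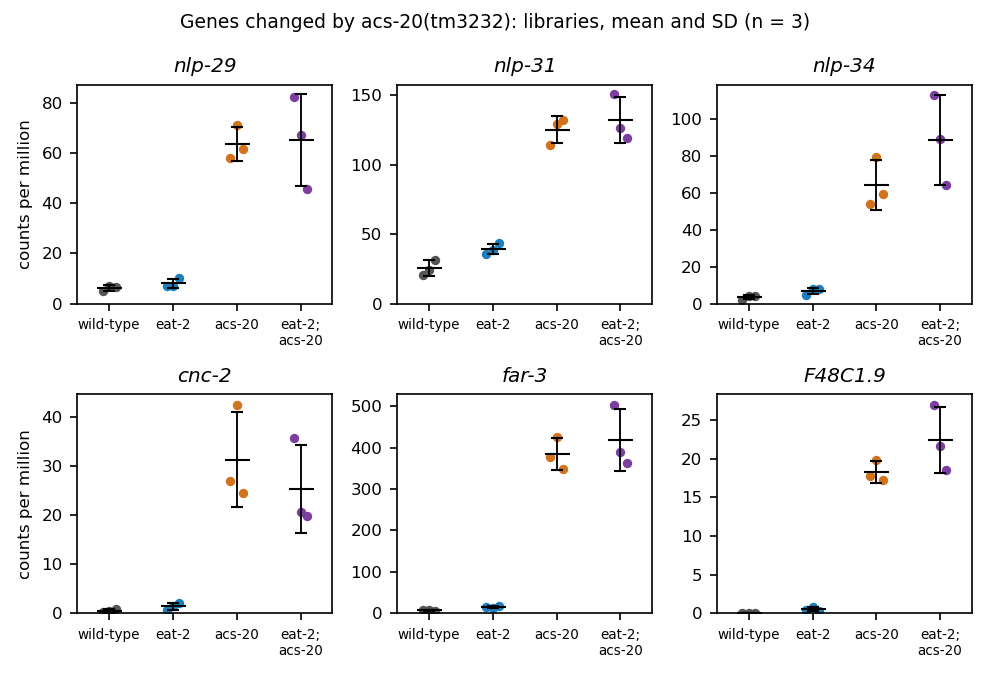
CPM (y axis) of nlp-29, nlp-31, nlp-34, cnc-2, far-3 and F48C1.9 by genotype (x axis), with 1 dot per library and the mean and SD of 3. nlp-29 averages 6.19 in wild-type, 8.05 in eat-2, 63.6 in acs-20 and 65.2 in the double mutant.

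Of 14 epidermal antimicrobial peptide genes 10 rose and none fell (the same counts adjusted over the list alone; adjusted p = 0.00345 with an estimated correlation), with a median log2 of 2.30. nlp-31 (2.29, SE 0.149, adjusted p = 1.78e-06) and nlp-29 (3.36, SE 0.229, adjusted p = 4.96e-06) had among the smallest p. Among 102 C-type lectin genes 8 fell and none rose (15 and 1 adjusted over the list alone; adjusted p = 0.588), including clec-229 (-2.04) and clec-3 (-1.85). Fatty acid beta-oxidation had 5 genes down and none up of 43 (8 and 0 adjusted over the list alone; adjusted p = 0.825), among them acdh-2 (-2.77) and ech-6 (-0.96), while fat-5 rose (1.28). Of 15 pharyngeal markers, gland genes among them, 3 fell and none rose (5 and 1 adjusted over the list alone; adjusted p = 0.866): myo-1 (-1.19, SE 0.158), myo-2 (-1.19, SE 0.17) and the troponin T gene tnt-4 (-1.46, SE 0.204). Hedgehog-related and patched-related genes had 2 up and 2 down of 61, with wrt-4 (-1.44) among the falls. Other changed genes included ugt-33 (2.53), the ferritin gene ftn-1 (1.87), the small heat shock gene hsp-12.3 (-1.80), the lysozyme gene lys-6 (-1.13) and nhr-11 (1.48). No vitellogenin gene was called (adjusted p of the list = 0.9), and cuticle collagens had 2 up and none down of 134 (adjusted p = 0.871). The count of changed genes was 179 without wild-type replicate 1 and 161 without acs-20 replicate 3, and in the latter 89 rose and 72 fell. Increases and decreases numbered 106 and 93 among changes of at least 2-fold, 170 and 369 without a filter and 106 and 210 without acs-20 replicate 2.

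The comparison of the double mutant with wild-type asked what both mutations change together. Changes of each single mutant were found side by side: nlp-29 stood at 65.2 ± 18.4 CPM (SD, n = 3) against 6.19 ± 1.14 in wild-type, far-3 at 418 ± 75.5 against 6.91 ± 0.27, vit-1 at 15.2 ± 1.62 against 236 ± 59, and clec-70 at 19.1 ± 1.21 against 0.83 ± 0.172. hmit-1.1 reached 1.02 ± 0.393 from 30.7 ± 2.87. Changed genes numbered 2526, 1286 up and 1240 down, and 905 of them changed by at least 2-fold.

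Highest among the increases under the naming rule were F48C1.9 (at least 220-fold, with no counts in wild-type), srlf-34 (log2 6.63), T22F3.11 (6.09), ugt-18 (6.003), far-3 (5.92, SE 0.172, adjusted p = 1.44e-10), cnc-2 (5.63), ptr-22 (5.49) and nlp-34 (4.65). vit-4 (-7.69), vit-3 (-6.68), pud-3 (-6.18), hmit-1.1 (-4.85, SE 0.277, adjusted p = 1.78e-07), pud-1.2 (-4.22), C30G12.2 (-3.88), the acyl-CoA oxidase gene acox-1.2 (-3.27) and Y48E1B.8 (-3.23) were lowest under that rule. fat-7 fell (-1.26, adjusted p = 0.00044), as did gpdh-1 (-1.74, adjusted p = 0.000691) and gst-4 (-0.82, adjusted p = 0.00507).

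Of the 14 epidermal antimicrobial peptide genes 12 rose and none fell (13 and 0 adjusted over the list alone; adjusted p = 0.0376), among them nlp-31 (2.37), nlp-29 (3.39) and nlp-34 (4.65), but the list was past 0.05 in 9 of the 12 leave-one-out fits, which gave 0.0154 to 0.112. All 6 vitellogenin genes fell (adjusted p = 0.169), vit-1 by -3.95 (SE 0.274) and vit-2 by -2.66 (adjusted p = 0.025, not called without wild-type replicates 1 or 2 or any 1 of the double mutant libraries, up to 0.0831), and 6 of 9 adult cuticle genes fell with them (adjusted p = 0.171), for example col-38 (-1.07) and rol-1 (-1.12). Sphingolipid genes had 9 up and 1 down of 26 (12 and 1 adjusted over the list alone; adjusted p = 0.169), with asm-2 (1.73) and asah-1 (1.37) rising. Nuclear-encoded genes of oxidative phosphorylation had 25 down and 1 up of 43 (29 and 1 adjusted over the list alone; adjusted p = 0.621), such as nuo-1 (-0.50) and lpd-5 (-0.49) down and asg-1 (0.57) up. In fatty acid beta-oxidation 19 fell and 4 rose (24 and 5 adjusted over the list alone; adjusted p = 0.312), with acdh-2 (-4.77) and ech-6 (-1.40) down and ech-9 (4.32) up. Of 26 autophagy genes 6 rose and none fell (8 and 0 adjusted over the list alone; adjusted p = 0.743), including sqst-1 (0.79) and lgg-2 (0.90). Collagen genes had 38 down and 11 up of 134 (45 and 15 adjusted over the list alone; adjusted p = 0.659), and col-98 (2.14) and col-42 (2.14) rose. The number of changed genes was 1573 without wild-type replicate 1, 1581 without wild-type replicate 3, 1676 without double mutant replicate 1 and 1602 without double mutant replicate 2. Increases and decreases numbered 1140 and 1415 with RLE factors, 1127 and 1519 in DESeq2 and 636 and 269 among changes of at least 2-fold, and decreases were the more numerous in 7 of the 12 leave-one-out fits.

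Comparing the double mutant with eat-2 measured the effect of the acs-20 mutation in eat-2 mutants. nlp-29 rose from 8.05 ± 1.84 to 65.2 ± 18.4 CPM (SD, n = 3), nlp-34 from 6.84 ± 1.75 to 88.9 ± 24.6, and far-3 from 15.7 ± 2.42 to 418 ± 75.5. clec-70 fell from 65.6 ± 14.3 to 19.1 ± 1.21, and the lectin gene clec-52 from 45.6 ± 15.5 to 12.9 ± 2.69. There were 304 changed genes, 195 up and 109 down, and 198 of them changed by at least 2-fold.

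F48C1.9 (log2 5.41), far-3 (4.73, SE 0.16, adjusted p = 1.12e-09), srlf-34 (4.59), cnc-2 (4.12), nlp-34 (3.68), the cation-transporting ATPase gene catp-3 (3.66), the phosphatase gene pho-6 (3.64) and cnc-4 (3.61) were highest under the naming rule. Lowest under that rule were Y48E1B.8 (-2.85), clec-230 (-2.05), hmit-1.1 (-1.86), clec-52 (-1.81), wrt-4 (-1.78), sdz-24 (-1.71), acox-1.2 (-1.49) and nspc-20 (-1.46). The call of acox-1.2 ended in 6 of the 12 leave-one-out fits, with adjusted p up to 0.164. Of the 14 epidermal antimicrobial peptide genes 10 rose and none fell (13 and 0 adjusted over the list alone; adjusted p = 0.00641 with an estimated correlation), among them nlp-29 (3.00, SE 0.224) and nlp-31 (1.74, SE 0.145). C-type lectins had 2 up and 4 down of 102 (5 and 13 adjusted over the list alone; adjusted p = 0.714). fat-7 fell (-1.13, adjusted p = 0.00412), nhr-80 fell (-1.05) and nhr-11 rose (1.98), as did ptr-22 (2.37) and ugt-33 (2.61). The count of changed genes was 154 without eat-2 replicate 3, 155 without double mutant replicate 1 and 174 without double mutant replicate 2. Increases and decreases were near balance without wild-type replicate 2 (212 and 199) and without eat-2 replicate 2 (120 and 132).

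Comparing the double mutant with acs-20 measured the effect of the eat-2 mutation in acs-20 mutants. vit-1 fell from 240 ± 70.3 to 15.2 ± 1.62 CPM (SD, n = 3), and clec-70 rose from 0.532 ± 0.18 to 19.1 ± 1.21. dod-24 rose from 16.17 ± 3.44 to 97.3 ± 6.11, and the lipase gene lipl-1 from 1.14 ± 0.638 to 22.3 ± 4.54. Changed genes numbered 1863, 1099 up and 764 down, and 748 of them changed by at least 2-fold.

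Under the naming rule, with its limits on average CPM, overlap of samples and genes per family, fold increases were highest for ugt-18, with a counting ratio of 130 (95% interval 44.1 to 631), ech-9 (log2 5.998, SE 0.29, adjusted p = 1.24e-07), clc-11 (5.90), T22F3.11 (5.22), clec-70 (5.10), C08E3.13 (4.74), lipl-1 (4.21) and the tetraspanin gene tsp-2 (4.07). vit-4 (-6.83), vit-3 (-5.80), hmit-1.1 (-3.07), pud-3 (-3.07), pud-1.2 (-2.83), K07H8.16 (-2.75), drd-5 (-2.40, SE 0.164) and acox-1.2 (-2.28) fell furthest under that rule. None of the 41 lists was called by camera with an estimated correlation. The smallest adjusted p was 0.138, 5 lists had an unadjusted p under 0.05, and camera with the preset correlation called 16 and fry 11. All 6 vitellogenin genes fell (adjusted p = 0.138), though the call of vit-2 (-2.58, adjusted p = 0.036) ended in 6 of the 12 leave-one-out fits (up to 0.11). C-type lectins had 32 up and 5 down of 102 (34 and 7 adjusted over the list alone; adjusted p = 0.138), among them clec-42 (5.62) and clec-17 (5.14). Targets of PMK-1 had 6 up and none down of 12 (8 and 0 adjusted over the list alone; adjusted p = 0.138), with dod-24 (2.58) and dod-22 (2.13). Neuropeptide and insulin genes had 26 up and 1 down of 96 (37 and 1 adjusted over the list alone; adjusted p = 0.532), for example ins-7 (1.79), ins-4 (2.39) and flp-8 (1.36). Genes of oxidative phosphorylation had 20 down and 1 up of 43 (32 and 1 adjusted over the list alone; adjusted p = 0.53), including cox-7C (-0.44) and atp-2 (-0.34). Pharyngeal markers had 7 up and none down of 15 (9 and 0 adjusted over the list alone; adjusted p = 0.512), and body wall muscle genes 8 down and none up of 17 (10 and 1 adjusted over the list alone; adjusted p = 0.485), such as mup-2 (-0.52) and unc-27 (-0.49). The count of changed genes was 1061 without acs-20 replicate 1, 919 without acs-20 replicate 3, 1008 without double mutant replicate 1 and 999 without double mutant replicate 2. In DESeq2 1053 rose and 1015 fell, and among changes of at least 2-fold 605 rose and 143 fell.

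Whether each mutation acts alike in both backgrounds was measured on libraries that the paired contrasts do not share. Of the 1103 genes changed by eat-2 in the intact background, 91.8% moved the same way between acs-20 and the double mutant, 97.1% of those up and 85.7% of those down. Of these, 695 (63%) were also called in the same direction and 8 in the opposite one, against 45.3 up and 27.1 down if the lists were independent. As sets, both moved on balance in their own direction: the fry test of limma gave a two-sided p of 6.01e-06 for the genes up and 2.12e-05 for the genes down. ugt-18, clec-70, ech-9, vit-1 and hmit-1.1 were among the genes called in both. Of the 318 genes changed by acs-20, 89.3% moved the same way between eat-2 and the double mutant, and 126 (39.6%) were called in the same direction and 2 in the opposite one. Their fry values were 1.26e-06 for the genes up and 0.000521 for the genes down. Without acs-20 replicate 2 the share fell to 69.6%, with a fry p of 0.18. far-3, nlp-29, cnc-2, clec-230 and wrt-8 were called in both backgrounds. Across all tested genes, which are not independent replicates, Pearson's r of the 2 changes was 0.603 for eat-2 and 0.402 for acs-20.

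**Figure D4:**
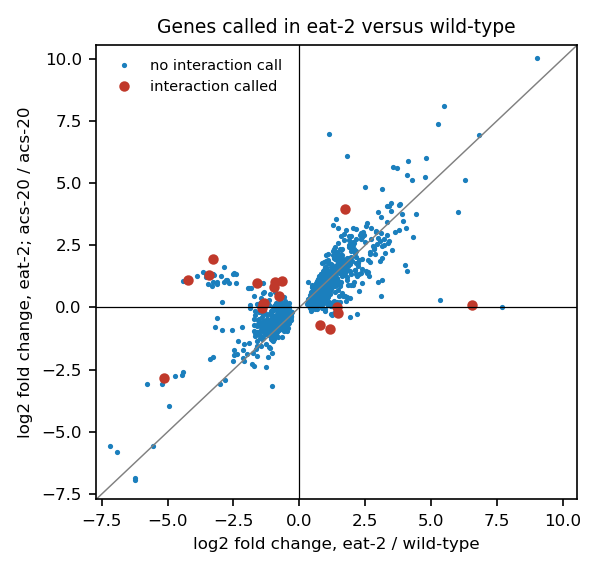
Log2 fold change of the 1103 genes changed in eat-2 against wild-type (x axis) plotted against their log2 fold change in the double mutant against acs-20 (y axis), with 1 point per gene and the genes called in the interaction in red. The same direction is shown by 91.8% of them, and 18 are red.

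The interaction asked for which genes the effect of eat-2 depends on acs-20. It called 27 genes, 20 with a more positive effect of eat-2 in acs-20 mutants and 7 with a more negative one. dod-24 stood at 116 ± 3.31 CPM in wild-type and 114 ± 21.7 in eat-2, at 16.17 ± 3.44 in acs-20, and at 97.3 ± 6.11 in the double mutant (SD, n = 3 each). The myosin gene myo-2 stood at 78.7 ± 4.71, 49.9 ± 4.89, 34.4 ± 10.8 and 71.2 ± 5.01 in the same order, and myo-1 at 89 ± 13, 62.4 ± 9.76, 39 ± 8.53 and 70.5 ± 4.64. spp-23, a saposin-like gene, was higher in each single mutant (65.1 ± 7.01 in eat-2 and 58.5 ± 3.63 in acs-20) than in wild-type (38 ± 1.94) or the double mutant (35.6 ± 6.11).

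**Figure D5:**
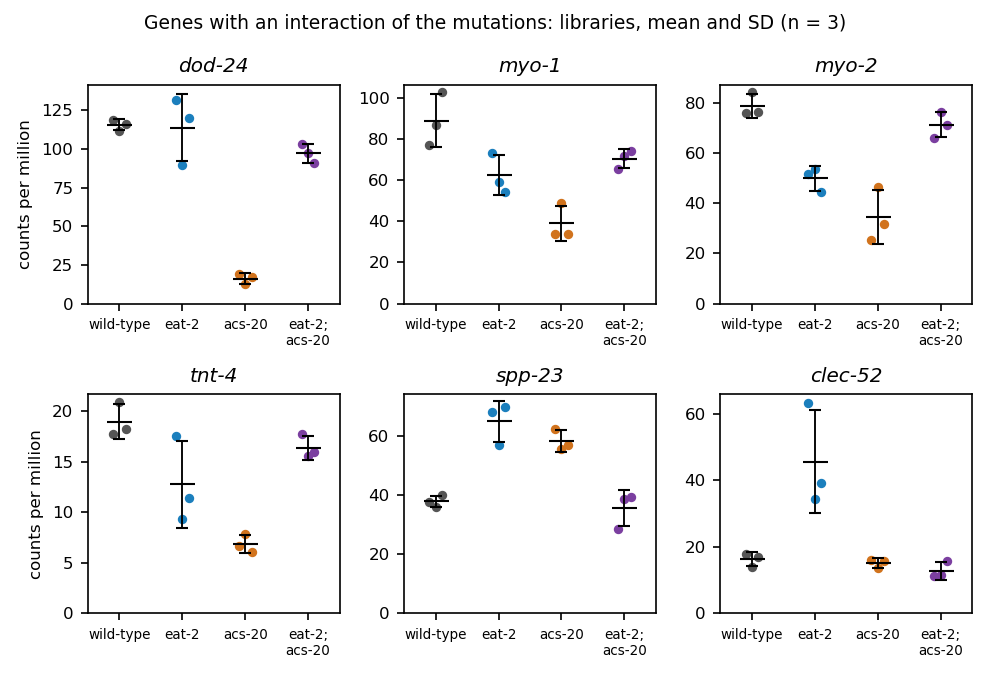
CPM (y axis) of dod-24, myo-1, myo-2, tnt-4, spp-23 and clec-52 by genotype (x axis), with 1 dot per library and the mean and SD of 3. dod-24 averages 116 in wild-type, 16.17 in acs-20 and 97.3 in the double mutant.

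Among called genes with an average log2 CPM of at least 3, interaction values were highest for dod-24 (log2 2.61, SE 0.218, adjusted p = 8.64e-05), lron-2 (2.57), pud-1.2 (2.29), T19C9.8 (2.2), Y43F8B.3 (1.95, SE 0.216, adjusted p = 0.000901), tnt-4 (1.83) and lgx-1 (1.79), and myo-2 had 1.71 (SE 0.238, adjusted p = 0.00906). They were lowest for F22F7.7 (-2.07), Y42G9A.3 (-2.04, SE 0.211, adjusted p = 0.000469), clec-52 (-1.71) and spp-23 (-1.49, SE 0.178, adjusted p = 0.00195). The calls of dod-24, Y43F8B.3, Y42G9A.3 and spp-23 held in all 12 leave-one-out fits and that of myo-2 in 11 (0.0559 without eat-2 replicate 3). Those of lgx-1, myo-1, lron-2, clec-52, F22F7.7, T19C9.8, tnt-4 and pud-1.2 ended in 9, 8, 8, 8, 8, 6, 5 and 5 of them. Of the 15 pharyngeal markers 3 were called, all with a positive interaction (5 adjusted over the list alone; adjusted p = 0.863). No list was called by camera with an estimated correlation, where 1 list had an unadjusted p under 0.05, or by fry, while the preset correlation called 16. The number of genes called was 150 without acs-20 replicate 2, 69 without wild-type replicate 3 and 8 to 17 in 9 of the other fits: 16 without wild-type replicate 1, 14 without wild-type replicate 2, 14 and 8 without eat-2 replicates 2 and 3, 11 and 12 without acs-20 replicates 1 and 3, and 11, 17 and 15 without double mutant replicates 1, 2 and 3. The positive majority was gone without eat-2 replicate 2 (7 and 7) or 3 (4 and 4) and small without acs-20 replicate 1 or double mutant replicate 1 (6 and 5 in each) or acs-20 replicate 3 (7 and 5), while without acs-20 replicate 2 it was 132 to 18.

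The single mutants shared 75 genes changed in the same direction against wild-type, 35 up and 40 down, where independent lists would share 5.85 and 6.24, and 20 genes changed in opposite directions. Both contrasts use the same wild-type libraries, which raises such overlap by chance. In unchanged groups simulated from the wild-type means, a wild-type group included, the overlap was at most 1 gene. This held over 100 draws with genes drawn independently and 100 with deviations of whole libraries. Hardly any of these groups held enough calls in both contrasts to overlap, so the simulation sets no bound. Part of the excess over independent lists may come from the shared libraries. Over all 14390 tested genes the covariance of the 2 changes was 0.072 (Pearson's r 0.243). Simulated covariances were 0.0382 to 0.0457 with genes drawn independently and -0.0145 to 0.109 with deviations of whole libraries, where 4 of 100 reached the observed value. The observed r lay below the simulated r of independent genes (0.455 to 0.522) and within that of whole libraries (-0.282 to 0.909). Of the 75, 70 were also changed in the same direction in the double mutant, 34 up and 36 down. Shared increases included far-3 (eat-2 1.18, acs-20 5.80), nlp-31 (0.63 and 2.29), ptr-22 and fat-5 (1.45 and 1.28), and the nuclear hormone receptor gene nhr-87, which had 1 count in wild-type and counting ratios of 133 (95% interval 23.4 to 5300) in eat-2 and 89.1 (15.5 to 3570) in acs-20. hmit-1.1 (-2.995 and -1.78), pud-3 (-5.80 and -3.11), acdh-2 (-3.29 and -2.77) and ckb-2 were shared decreases. The number of shared genes was 30 without wild-type replicate 1, 48 without eat-2 replicate 3, 44, 124 and 39 without acs-20 replicates 1, 2 and 3.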

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

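The genes below drew attention because the test of the interaction found the effect of eat-2 to differ between animals with and without an intact acs-20. Tests chosen only after the result was seen were the one on fold sizes without single wild-type libraries, both tests on the share of the pharynx and the one on comparisons without wild-type libraries, while the covariates of stage and of ribosomal RNA were added once the data had been seen but before the values they tested.

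dod-24 had the highest interaction value among called genes with an average log2 CPM of at least 3 (log2 2.61). eat-2 left it at 114 CPM beside 116 in wild-type, but raised it from 16.17 to 97.3 where acs-20 was mutated. In pud-1.2 (2.29) the effect of eat-2 was negative in both backgrounds and smaller in acs-20 mutants. lron-2 had a value of 2.57, T19C9.8 of 2.2, Y43F8B.3 of 1.95, tnt-4 of 1.83, lgx-1 of 1.79, myo-2 of 1.71 and myo-1 of 1.36. Y42G9A.3 (-2.04) and spp-23 (-1.49) rose with either mutation alone. In the double mutant spp-23 was called lower than in either single mutant. Y42G9A.3 was called lower there than in acs-20 but not than in eat-2, and it stayed above wild-type (log2 0.62). clec-52 (-1.71) rose with eat-2 only where acs-20 was intact, and F22F7.7 had a value of -2.07. The calls of lron-2, pud-1.2, T19C9.8, tnt-4, lgx-1, myo-1, clec-52 and F22F7.7 ended in 5 to 9 of the 12 leave-one-out fits, and that of myo-2 in 1. Of 100 assignments of the 12 libraries to 4 groups, the real one included, 2 gave at least the 27 genes of the real one. The other 99 all mixed genotypes within groups, which carries the effects of eat-2 and acs-20 into the contrast and its spread, so this share does not decide whether chance gave the interaction. The highest other assignment gave 196, and its contrast set all wild-type and eat-2 libraries against all acs-20 and double mutant libraries, so the structure behind it is the effect of acs-20 over both backgrounds.

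The fall of the pharyngeal myosin genes myo-1 and myo-2 in acs-20, a mean log2 of -1.19, was weighed first. The SEs here measure the spread between genes read in the same libraries, not between libraries. A smaller share of the whole pharynx is argued against as the whole cause: the other 13 pharyngeal markers, gland genes included, had a median of -0.111 (SE over genes 0.286, range -1.46 to 1.75). With the stage score as a covariate the mean of myo-1 and myo-2 was -1.22. The score covered similar ranges in acs-20 (-0.927 to 1.58) and wild-type (-1.63 to 1.04), so it could shift this mean little whatever the cause. Developmental stage therefore stays open. A smaller share of pharyngeal muscle cells stays open, as the other contractile genes of the pharynx (myo-5, tni-4, tnt-4 and tnc-2) had a mean log2 change of -0.909 (SE over genes 0.228), which is also what a lower expression of contractile genes in unchanged cells would give. Both may contribute, and the return of myo-2 to 71.2 CPM in the double mutant was not explained by any test run here.

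The vitellogenin genes, lower in eat-2 than in wild-type by a median log2 of -5.25, were weighed second, because these genes switch on near the stage at which the worms were collected. In the stage score oocyte and sperm genes ranked high (median percentiles 98.4 and 95.3) and moulting genes low (7.35). Cuticle collagens (82.6) and pharyngeal markers (81.8) ranked high too, and adult cuticle genes near the middle (51.5), so the score may hold more or other than stage. With this score as a covariate the median was -4.95 and 6 of 6 genes were called, with a highest adjusted p of 0.018. With the ribosomal RNA share as a covariate it was -5.05 and 5 of 6 were called, with a highest adjusted p of 0.061. Scores were -1.09, 0.624 and -0.767 in eat-2, against -0.00653, 1.04 and -1.63 in wild-type, and 0.0135 to 1.15 in the double mutant, ranges that overlapped, while the mean log2 vitellogenin levels of 2.74 to 4.7 and 4.19 to 4.45 in these mutants lay apart from the 8.19 to 9.71 of wild-type. These values argue against a steady trend with this score or with ribosomal RNA as the whole cause. Stage differences that the score does not hold stay open. So do a sudden onset just after the collected stage, which a linear score could miss, and an effect of feeding on yolk genes. The lower adult cuticle genes of eat-2 (7 of 9 over the list alone, none over all genes) would go with such an onset.

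The 70 genes changed the same way in all 3 mutant strains were weighed last, since every such comparison uses the same 3 wild-type libraries. In 100 simulations each of independent genes and of whole-library deviations in unchanged groups the highest number was 0. This decides nothing, as no simulation held 70 calls in both single mutants. In the comparisons of the double mutant with eat-2 and with acs-20, which use no wild-type library, these genes moved on in their shared direction. The median log2 was 0.433 and 0.513 (two-sided p of 2.46e-05 and 1.54e-05 by the fry test of limma, 58 of 70 genes in both). The genes and their directions had been picked by calls that used the same mutant libraries, and both comparisons share the double mutant libraries. These values therefore do not decide how much of the number came from chance shared through the wild-type libraries. With the stage score as a covariate 70 of the 70 were kept. That score is taken from the spread between these replicates, and with it 175 genes were called the same way in all 3, so keeping them does not decide on stage. A single deviating wild-type library was tested by leaving each out: 26 (37.1%), 45 (64.3%) and 33 (47.1%) of the genes stayed called without wild-type 1, 2 and 3, of which the first and last fell short of the planned limit, but leaving out a mutant library also ended calls (34 to 63 kept), so that limit measured the loss of samples as well. No log2 fold change fell below 0.699 of its size without any 1 wild-type library. But the genes had been picked by calls against these libraries, and in all 70 the wild-type libraries lay apart from all 9 mutant libraries. Such a choice leaves few genes that rest on 1 library, so the sizes do not decide on a single deviating library. A difference in strain background between wild-type and the mutants was not tested and may be part of the pattern.

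The count of changed genes was compared with other splits of the 6 libraries in each pairwise comparison. With 10 splits no share under 0.05 can be reached. The real split gave 1103 genes for eat-2 against wild-type, 2526 for the double mutant against wild-type, 304 against eat-2 and 1863 against acs-20. In edgeR's test the highest other split of each gave 0, so 1 of 10 splits, the real one itself, reached each real count. For acs-20 against wild-type the real split gave 318 and the highest other 89, in the split that joined wild-type 1 and 2 with acs-20 2. Every other split placed both genotypes in each group, which carries the effect of genotype into the spread and lowers the calls. These counts therefore do not decide whether chance gave the changed genes.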

How the results depend on the processing

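Chosen after seeing the data were the stage score, the ribosomal RNA share and the omission of ribosomal RNA genes; the other alternatives were set before. No call of a named gene reversed its direction with DESeq2, RLE factors, the replicate block or the stage score or in the leave-one-out fits, but the balance of increases and decreases did turn: from 593 up and 510 down in eat-2 against wild-type to 632 and 767 in DESeq2, from 1286 and 1240 in the double mutant against wild-type to 1127 and 1519, and from 142 and 176 in acs-20 to 89 and 72 without acs-20 replicate 3. Of 373 calls of named genes across the contrasts, 371 were kept by DESeq2, 372 with RLE factors, 373 with the replicate number as a block and 371 with the stage score. The labels do not say what a replicate number marks, and pairing was not seen throughout: of 18 pairs of libraries with 1 number in different genotypes, 9 correlated above 0.1 in their deviations from the group means (-0.091 to 0.43), and 7 of the 12 libraries correlated best with their own number, a hint from the data only. With RLE factors all 6 counts of changed genes stayed within 1.5 times, but no list was called in eat-2 against wild-type (0 instead of 3). DESeq2 gave 536 genes for the double mutant against eat-2 (296 shared with the 304) and 116 for the interaction (all 27 shared). Without a filter on low counts there were 539 genes for acs-20 against wild-type, 579 for the double mutant against eat-2, 99 for the interaction and 143 shared by the single mutants. A minimum change of 2-fold, stricter by construction, left 545 for eat-2 and 199 for acs-20 against wild-type, 905, 198 and 748 for the double mutant against wild-type, eat-2 and acs-20, and 40 shared genes. The replicate block gave 653 for the double mutant against eat-2, 56 for the interaction, and 0 lists for eat-2 and 0 for the double mutant against wild-type. With the stage score there were 1904 genes for eat-2 and 615 for acs-20 against wild-type and 111 for the interaction. The ribosomal RNA share gave 1231 for the double mutant against acs-20 and 44 for the interaction. Camera with the preset correlation called 15, 12, 22, 11, 16 and 16 lists in the 6 contrasts, and fry called 11 for eat-2 and 12 for the double mutant against wild-type and 11 for the double mutant against acs-20. A preset correlation ignores the correlation estimated within lists, and of its calls those of the 3 lists in eat-2 against wild-type and of the antimicrobial peptides in the 3 other contrasts held with the estimate. The cause of the other shifts was not tested.

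Leaving out 1 library, which also removes samples, gave 576 to 1272 genes for eat-2 against wild-type, 161 to 345 for acs-20 against wild-type, 1573 to 2676, 154 to 434 and 919 to 2026 for the double mutant against wild-type, eat-2 and acs-20, and 8 to 150 for the interaction. Lists called were 0 to 5, 1 to 2, 0 to 1, 1, 0 to 1 and 0. The eat-2 response kept its direction in 85.4 to 94.5% of genes and the acs-20 response in 69.6 to 92.7%, the lowest without acs-20 replicate 2. Shared genes numbered 30 to 124. Of the 373 calls of named genes 283 were kept in all 12 of these fits and 90 were lost in at least 1. Low counts limit genes such as eat-2 itself, with 0 to 3 reads per library.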

Other observations

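Families of genes, the propionate-pathway genes and the neuropeptide examples in this part were chosen after their values were seen, and the sentinel genes before.

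Of 6 genes picked from the breakdown of propionate by way of acrylyl-CoA, hach-1, hphd-1, ech-6 and dhgd-1 were called lower in both single mutants and in the double mutant. hach-1 stood at 299 ± 29.5 CPM in wild-type, 174 ± 25 in eat-2, 161 ± 6.98 in acs-20 and 103 ± 10.8 in the double mutant (SD, n = 3 each). Mean values of hphd-1 followed the same order, with 1049 ± 125, 695 ± 90.5, 601 ± 16 and 408 ± 65.4, as did ech-6 with 1040 ± 102, 721 ± 112, 537 ± 35.5 and 395 ± 56.7. Against wild-type the log2 changes of the double mutant were -1.54 for hach-1 (SE 0.123, adjusted p = 4.82e-06), -1.36 for hphd-1 (adjusted p = 1.36e-05), -1.40 for ech-6 (adjusted p = 1.28e-05), -1.01 for acdh-1 (adjusted p = 9.86e-05) and -0.86 for alh-8 (adjusted p = 0.000218). The partner enzyme gene dhgd-1 fell too (-1.19, adjusted p = 7.33e-06). acdh-1 and alh-8 were called lower in acs-20 (-0.66 and -0.50) and not in eat-2 (-0.33 each, adjusted p = 0.119 and 0.0992). The calls of all 6 genes in the double mutant against wild-type held in the 12 leave-one-out fits. In eat-2 the call of ech-6 ended without wild-type replicate 1 (0.064) or 3 (0.0916) or eat-2 replicate 2 (0.0632), and that of hphd-1 without wild-type replicate 3 (0.0521). In acs-20 the call of acdh-1 ended without acs-20 replicate 3 (0.0585), and those of dhgd-1 and alh-8 in 4 and 5 of the fits (up to 0.0779 and 0.162). The double mutant was called lower than both single mutants in all 12 fits only for hach-1 (against eat-2 -0.76, against acs-20 -0.65). Against acs-20 the call of ech-6 ended in 5 fits (up to 0.137), that of alh-8 in 6 (up to 0.151) and that of hphd-1 without double mutant replicate 2 (0.0548), and acdh-1 was not called (0.0709). Against eat-2 the calls of dhgd-1, alh-8 and acdh-1 ended in 4, 4 and 2 fits (up to 0.082, 0.122 and 0.0518). None of the 6 had an interaction past the threshold (adjusted p from 0.921 to 0.999). The nuclear hormone receptor genes nhr-10 and nhr-68, which activate this pathway, were not called in the double mutant against wild-type (log2 0.10 and -0.23, adjusted p = 0.663 and 0.227).

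In several families the called genes lay largely in one direction within a contrast. Genes of a family are often regulated together, which the hypergeometric test ignores, so its p values are too small to that extent. Of 12 abu genes, which encode proteins rich in glutamine and asparagine, 10 fell in eat-2 against wild-type (median log2 -3.04, adjusted p = 3.2e-11 by a hypergeometric test), while 3 rose in the double mutant against eat-2 (adjusted p = 0.0222) and 2 fell against acs-20, where the family median was positive (1.06). The call of abu-1 in eat-2 ended without any 1 of the eat-2 libraries (adjusted p = 0.0637, 0.0601 and 0.0662). Single libraries stood apart in abu-1, with 29.4, 32 and 9.93 CPM in wild-type replicates 1 to 3 and 4.44, 18.2 and 3.37 in those of acs-20, and wild-type replicate 3 and acs-20 replicate 2 also had the lowest and highest stage scores (-1.63 and 1.58). Of 13 nspc genes 10 fell in acs-20 against wild-type (median -2.01, adjusted p = 2.89e-15), and 8 fell in the double mutant against eat-2 (adjusted p = 1.87e-12), while 7 rose in the double mutant against acs-20 (adjusted p = 0.000762). Members of both families resemble each other closely, and reads with more than 1 position were set apart, so their counts may be too low. These counts may not be independent either. All 8 ndub genes, subunits of the first complex of the respiratory chain, fell in the double mutant against wild-type (median -0.36, adjusted p = 5.36e-07), although the list of other oxidative phosphorylation genes was not called there with an estimated correlation (adjusted p = 0.621). Of 30 flp neuropeptide genes 11 rose in the double mutant against acs-20 (median 0.60, adjusted p = 0.000621), and the list of neuropeptides and insulins that holds them was not called either (adjusted p = 0.532). Carboxylesterase genes of the cest family had 11 of 28 down in eat-2 (adjusted p = 1.11e-07) and acyl-CoA dehydrogenase genes 6 of 13 (adjusted p = 0.00012). Of 15 pals genes 5 rose in eat-2 (adjusted p = 0.0149) and 6 in the double mutant against wild-type (adjusted p = 0.0319). All 3 pud genes fell in each mutant strain against wild-type.

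Sentinel genes of heat, metal and moulting were mostly not past the threshold in eat-2. In eat-2 against wild-type this held for hsp-16.2 (-0.77, adjusted p = 0.662), mtl-1 (-1.06, adjusted p = 0.493), lipl-4 (0.24, adjusted p = 0.645), dpy-7 (0.16, adjusted p = 0.806), lin-42 (0.03, adjusted p = 0.955), mlt-10 (-0.21, adjusted p = 0.669), nas-37 (-0.36, adjusted p = 0.531) and col-19 (-2.33, adjusted p = 0.161). sysm-1 rose in eat-2 (1.05, adjusted p = 0.013), a call that ended without wild-type replicate 1 (0.0565) or 3 (0.0581). acs-22, the closest relative of acs-20, was lower in eat-2 (-0.53, adjusted p = 0.0201), but not without wild-type replicate 1 (0.063) or 3 (0.0844) or eat-2 replicate 2 (0.0647) or 3 (0.07), and it was not called in acs-20 (-0.25, adjusted p = 0.396). In the double mutant against wild-type mlt-10 fell (-1.05, adjusted p = 0.00836).

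The libraries also held reads that were not assigned to 1 gene. With the strand setting unknown, a read assigned to no gene need not lie outside all genes. Reads assigned to no gene made up 44.1 to 46.5% of the reads in the tables, reads with more than 1 position 5.21 to 9.99%, and reads in overlapping genes 0.611 to 0.728%. Ribosomal RNA took 2.09 to 6.29% of the counts in genes, with group means of 3.67 ± 2.28% in wild-type, 4.55 ± 1.11% in eat-2, 2.34 ± 0.224% in acs-20 and 4.43 ± 1.3% in the double mutant (SD, n = 3).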
